A study of Mus musculus with 12 samples.

How the data were processed

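The lateral choroid plexuses, the secretory epithelial tissue of the lateral brain ventricles, were taken from adult mice with an intact Abhd2 gene (called wt in the labels) or with both copies of Abhd2 inactivated (called hoz). Per the labels' protocols, all animals were killed around 10 in the morning, the females in proestrus, the tissue was snap frozen, mRNA was selected on oligo dT beads, and libraries were made with a KAPA RNA HyperPrep kit and sequenced as paired reads of 100 bases on an Illumina HiSeq instrument. Whether each library holds the tissue of 1 animal or of several is not given in the sources used here, so the p-values below measure the spread between these libraries. The 12 libraries form 4 groups of 3: wt males, hoz males, wt females and hoz females. Groups were taken from the labels. Libraries within a group are numbered in the order in which they are listed, and no number links a library of 1 group to a library of another.

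The deposited table holds 35275 genes. Its read count columns hold raw reads per gene and library, counted by the authors and not normalized, per the file headers and a check that every value is a whole number. The genome build is mm10 and the tools listed are CASAVA, TopHat, DESeq2, STAR-Fusion, STAR 2.5, HTSeq 0.6.1 and edgeR 3.16.5, per the submitters' processing notes, which do not tie each tool to a step. The deposited FPKM columns equal the reads per kilobase of the deposited gene length and scaled to the library's summed reads, with a largest relative difference of 4.97e-12 over 218198 values, so they hold no information beyond the counts and were used only for that check. The deposited gene length in bases is given per gene. The deposited log2 fold change columns give the first named group over the second, per the file headers. The deposited p-value and adjusted p-value columns come from the authors' own tests, whose adjustment method is not given in the sources used here. Their calls are set beside those computed here. Of the 35275 gene identifiers, 34490 were found in GENCODE release M21 for mm10 and 24919 had identical coordinates there. Coordinates below are those of the deposited table.

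Whether the reads were counted by strand is not given in the sources used here. Of the 94 genes taken from the contrasts by the naming rule given below, 41 overlap the span of another gene and 38 overlap one on the opposite strand. Genes named only in other ways are not in these counts. Reads of such pairs could be shared if strand was not used, which was not tested. Close relatives such as Scd1 and Scd2, the class I and class II antigens of the H2 cluster, the Gbp genes, the globins and the X and Y copies of Ddx3, Kdm5, Eif2s3 and Kdm6a with Uty can share reads, and their values are uncertain to that extent.

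Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with too few reads were removed with edgeR's filterByExpr by group, which left 13857. Libraries were scaled with TMM factors, and CPM below use the scaled library total. Means are given with the SD over the 3 libraries of a group. Genes were tested with edgeR's quasi-likelihood test on the 4 group means, with robust dispersion and 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 13857 genes, and a gene was called at an adjusted p under 0.05 with no fold threshold. The standard error (SE) of a log2 fold change is its size over the square root of the F statistic. The contrasts were hoz against wt in males, in females and as the mean over both sexes, female against male in wt and in hoz, and the interaction, which is the female genotype contrast minus the male one. All are two-sided. The males and females share no library, so the genotype contrasts of the sexes compare separate libraries, as do the sex contrasts of the genotypes. Their p-values are not fully independent, because the fit gives each gene a single variance estimate over all 12 libraries.

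Gene lists and the rule for naming genes were fixed before the data were examined. Abhd2 is always named. In each contrast the rule takes, among called genes with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups compared, the 10 with the largest rise and the 10 with the largest fall, leaving out predicted and clone symbols. It adds up to 4 called members of each list with the smallest p, allows the measured Y linked and X inactivation genes, called or not, and, as levels, up to 4 markers per cell type. Where fewer than 10 genes were called, all are named, with the 5 smallest p among genes not called. Other genes named were chosen after their values were seen. In the wt sex contrast these include called list members beyond the 4: Npas2, Bhlhe41, Hlf, Nr1d2, Cry2, Tef, Ifit1, Irf7, Manf and Pdia6. The 30 lists were choroid plexus epithelium, ion and water transport, motile cilia, neurons, astrocytes, oligodendrocytes, endothelium, mural cells, fibroblasts and matrix, macrophages, MHC class II, lymphocytes and granulocytes, erythroid, interferon response, immediate early genes, circadian clock, steroid hormone receptors and progesterone binding proteins, steroid synthesis and metabolism, abhydrolases and endocannabinoid metabolism, calcium and TRP channels, cholesterol synthesis, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal proteins, unfolded protein response, cell cycle, secreted growth factors and binding proteins, tight junctions and polarity, Y linked, and X inactivation and escape. Slc6a6 stands in the last list although it lies on chromosome 6, a mistake of the list that was left as fixed. A list was tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and limma's fry, which tests whether the members move on balance 1 way, were run beside it. A member count "adjusted over the list alone" adjusts the edgeR p over that list.

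The procedure was tested on simulated data. Counts were drawn from each gene's mean over all 12 libraries, its fitted dispersion and the library sizes, with known fold changes in a random set of genes. In the simulated male genotype contrast, 64.0% of genes changed 1.5-fold, 83.7% of those changed 2-fold and 96.0% of those changed 4-fold were recovered by edgeR, out of 13716 genes. The shares were 58.0%, 66.0% and 91.8% in the female genotype contrast with 13723 genes, and 34.7%, 58.0% and 84.0% in the interaction with 13726 genes. Of genes changed 1.25-fold, 32.0%, 27.1% and 0% were recovered in the male genotype contrast, the female one and the interaction. False calls were 15 of 152, 4 of 124 and 8 of 96. Each fold was given to 48 to 50 of the tested genes. The real contrasts called 1, 2 and 1 genes, so a gene there needed a smaller unadjusted p to pass. The shares recovered are therefore too high as a guide to the power of the real contrasts. No recovered gene had the wrong sign, and 0 of 20 unchanged lists were called by camera in each simulated contrast, with the preset correlation or the estimated one. Genes were drawn independently of each other, so this does not test whether the preset correlation is high enough for real data.

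The deposited read counts sum to between 5975707 and 47903184 per library. A gene at 0 reads was set against a limit of 3 reads over the group, and that limit covers counting error only. Alternatives set before the data were examined were relative log expression and upper quartile factors, no filter and a stricter one of 5 CPM in at least 3 libraries, DESeq2, limma voom with and without sample weights, a fit on the groups compared alone, scores of the neurons list and of the fibroblasts and matrix list as covariates, protein coding genes only, a fold of at least 1.5, an additive model, and leaving out each library in turn. Added after the data were seen were thinning of every library to the smallest total, the slope of each library's log2 CPM on gene length as a covariate, and leaving out 3 libraries that stand apart by their list scores. The fusion tool's output and the raw reads were not used here.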

Results

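RNA of the lateral choroid plexus was sequenced from wt and hoz mice of both sexes, with 3 libraries per group. The series compares the tissue with and without Abhd2, a lipid hydrolase of the alpha/beta hydrolase family that progesterone activates in sperm, in males and in females in proestrus. Summed reads per library were 18252548, 30120598 and 24874996 in wt males, 11842276, 43914129 and 47903184 in hoz males, 8011557, 14907449 and 32154836 in wt females, and 16000137, 7238147 and 5975707 in hoz females. The shallowest library was hoz female 3. A gene at 3 reads stood there at 0.502 CPM, against 0.0626 CPM in the deepest library of the series. The common biological coefficient of variation was 0.0870. Libraries of a group differed by more than sampling noise in every pair, with a chi-square per gene of 2.99 to 20.7.

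Transcripts of the choroid plexus epithelium dominated every library. Ttr, which encodes the thyroid hormone carrier transthyretin, took 9.05% to 10.9% of the reads, and the 10 most abundant genes took 20.4% to 22.7%. Mean levels over the 12 libraries were 56479 CPM for Enpp2 (the enzyme autotaxin), 4990.3 CPM for Kl (klotho), 2621 CPM for Clic6 (an intracellular chloride channel) and 216 CPM for Foxj1, the master regulator of motile cilia. Markers of other cells were lower but present: 46.9 CPM for Kdr of endothelium, 66.8 CPM for Rgs5 of pericytes, 720.2 CPM for Ptgds of the meningeal stroma, 20.2 CPM for Cd74 of antigen presenting cells, 86.9 CPM for Mbp of myelin and 109 CPM for Rtn1 of neurons. None of the genes of the lymphocytes and granulocytes list passed the filter on low counts. Some libraries stood apart by these markers. The mean log2 CPM of the neurons list lay 1.11 above the mean of all libraries in wt male 1 and 0.60 above it in hoz female 1. The endothelium list lay at -0.94 in wt male 2 and 0.72 in wt female 3, which also had the highest scores for interferon response, 0.80, and MHC class II, 1.24. In hoz female 2 the mural cells list lay at -0.74 and the macrophages list at -0.61. The first principal component held 25.9% of the variance and separated the sexes, while the second held 17.7% and set hoz female 2 apart (-38.1). The third held 11.5% and set apart hoz female 3, the shallowest library (-34.6).

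Abhd2 mRNA was almost gone from every hoz library. Abhd2 (ENSMUSG00000039202, chromosome 7, 79273201 to 79365508, plus strand, mm10) was read at 1987, 1862 and 2332 CPM in the wt males and at 48.7, 54.8 and 54.6 CPM in the hoz males, which is 2060.3 ± 244 against 52.7 ± 3.47 (SD, n = 3). The wt females had 2364, 2433 and 2430 CPM and the hoz females 54.4, 49.6 and 60.8 CPM, or 2409 ± 39.0 against 54.9 ± 5.62 (SD, n = 3). The level that remained was 2.56% in males and 2.28% in females. In log2 terms Abhd2 fell by 5.28 in males (SE 0.0979) and by 5.46 in females (SE 0.101), each with an adjusted p of 1.36e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the interaction of sex and genotype was -0.18 (SE 0.122, adjusted p = 1.0). The lowest hoz library still held 356 reads of the gene, well above the limit of 3 reads. Which part of the gene these reads cover cannot be read from counts per gene.

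**Figure D1:**
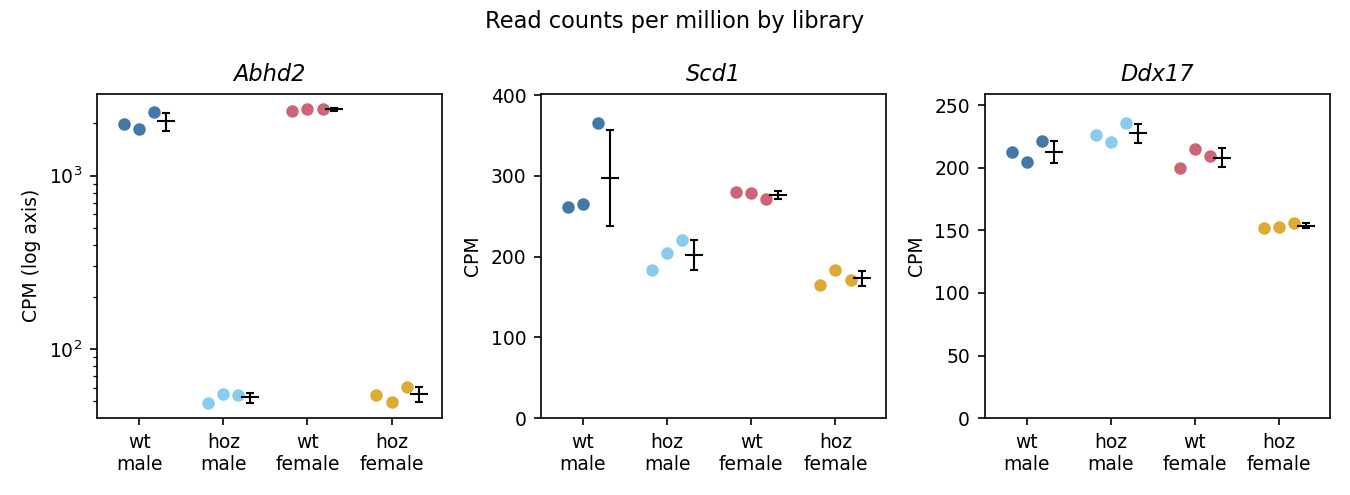
Abhd2, Scd1 and Ddx17 in CPM per library (y axis, logarithmic for Abhd2) for the 4 groups of 3 libraries (x axis), with a black dash at the mean and a bar of ± 1 SD. Abhd2 lay between 48.7 and 60.8 CPM in the hoz libraries, and Ddx17 was lowest in the hoz females, at 154 ± 2.06 CPM.

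In males, Abhd2 was the 1 gene called among 13857 by edgeR at an adjusted p under 0.05. Scd1, the stearoyl-CoA desaturase, and Pcsk2, a prohormone convertase, were not called, although each was lower in every hoz male than in every wt male, at 183 to 220 against 261 to 365 CPM for Scd1 and 42.8 to 47.5 against 59.8 to 68.8 CPM for Pcsk2. At an unadjusted p under 0.05 there were 301 genes, where chance alone gives 693. Besides Abhd2, the genes with the smallest p were Pcsk2 (log2 fold change -0.52, SE 0.0902, adjusted p = 0.204), Scd1 (-0.55, SE 0.109, adjusted p = 0.910), Lrrc38 (0.47, SE 0.103), Col17a1, a transmembrane collagen (-0.33, SE 0.0760), and Ackr4, a chemokine scavenging receptor (-1.20, SE 0.249), the last 3 with an adjusted p of 1.0. The counts by other tools were 4 genes with DESeq2, 1 with limma voom and 3 with voom and sample weights. With each library's gene length slope as a covariate, a setting chosen after the data were seen, edgeR also called Scd1 (-0.56, adjusted p = 3.80e-05). The authors' deposited table calls 3 genes, among them Pcsk2 and Ackr4 with adjusted p of 1.22e-04 and 5.61e-06.

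No gene list of the male genotype contrast contained a called gene other than Abhd2 itself, which is not in a list. The neurons list had a median log2 fold change of -0.52 with 1 of 25 members above 0 (camera adjusted p = 1.98e-08), beside the high neuron score of wt male 1 given above. The oligodendrocytes list had a median of -0.38 (15 genes, camera adjusted p = 0.00482). Cholesterol synthesis lay at a median of -0.10 with 0 of 23 members above 0 (camera adjusted p = 1.98e-08). Interferon response lay at 0.17 with 20 of 23 members above 0 (camera adjusted p = 2.14e-06) and erythroid at 0.38 (7 genes, camera adjusted p = 0.0137). With an estimated correlation none of these passed: adjusted p = 0.718 with an estimated correlation for cholesterol synthesis and adjusted p = 0.801 with an estimated correlation for the other 4. Adjusted over the list alone, 0 members passed in each of them. The lists closest to the tissue's own functions were not called, with medians of -0.01 for choroid plexus epithelium (36 genes), 0.00 for ion and water transport (36), -0.02 for motile cilia (59), 0.01 for tight junctions and polarity (28) and -0.02 for calcium and TRP channels (30). The same held for steroid hormone receptors and progesterone binding proteins (0.00, 19 genes), steroid synthesis and metabolism (-0.03, 14), abhydrolases and endocannabinoid metabolism (0.01, 27), unfolded protein response (-0.01, 26), immediate early genes (-0.04, 24), cell cycle (-0.02, 20), nuclear oxidative phosphorylation (-0.01, 43) and secreted growth factors and binding proteins (-0.03, 34). The mural cells and the fibroblasts and matrix lists had medians of 0.08 and 0.03 but a test direction of lower, the median and mean differed in sign for abhydrolases, calcium and TRP channels, unfolded protein response, and tight junctions, and none of these was called. Without wt male 3, 8 genes were called in place of 1, and without wt male 2 there were 2. Of the 5 list calls 2 were lost without some single library and 4 were lost or moved by over 1.5 times. Neurons lay at -0.12 without wt male 1 (adjusted p = 0.0273), -0.31 without hoz male 3, -0.86 without wt male 2 and -0.96 without hoz male 2. Oligodendrocytes lay at -0.18 without wt male 1 (adjusted p = 0.189) and -0.14 without hoz male 3 (adjusted p = 0.497). Erythroid lay at 0.13 without wt male 1 (adjusted p = 0.623), 0.14 without hoz male 2 (adjusted p = 0.224), 0.26 without wt male 3 (adjusted p = 0.103) and 0.73 without wt male 2, and interferon response at 0.10 without hoz male 3.

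In females, Ddx17, an RNA helicase of the DEAD box family that takes part in splicing and transcription, was lower in hoz. It fell by 0.44 on the log2 scale (SE 0.0565, adjusted p = 0.00493), from 208.0 ± 7.73 to 154 ± 2.06 CPM (SD, n = 3), with every hoz female below every wt female. Ddx17 and Abhd2 were the 2 genes called by edgeR. Close to the threshold lay Hspb1, a small heat shock protein (log2 fold change -0.56, SE 0.0905, adjusted p = 0.0528), and Scd1 (-0.68, SE 0.113, adjusted p = 0.137). Further off were Inmt, an amine methyltransferase (-0.85, SE 0.160, adjusted p = 0.283), Herc3, a ubiquitin ligase (0.41, SE 0.0843, adjusted p = 0.368), and Ptn, the growth factor pleiotrophin (-0.89, SE 0.188, adjusted p = 0.459). At an unadjusted p under 0.05 there were 940 genes, where chance gives 693, and DESeq2 called 7. The authors' deposited table calls 27 genes, with Scd1 at an adjusted p of 2.75e-24. It also calls Hspb1, Inmt, Herc3 and Ptn, with adjusted p of 0.00678, 1.56e-05, 0.00735 and 0.0446. Ddx17 overlaps Kdelr3, whose reads cannot be told from its own if strand was not used. The Ddx17 call was lost without wt female 2 (adjusted p = 0.0838), hoz female 1 (0.0752) or hoz female 2 (0.0750). A fit on the 2 female groups alone called 39 genes, and without wt female 1 there were 3.

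In the hoz females, 12 lists were called by camera with its preset correlation, 0 with an estimated correlation and 0 by fry, and none of their members was called over all genes. Interferon response had a median log2 fold change of -0.58 with 1 of 23 members above 0 (camera adjusted p = 1.60e-08), and adjusted over the list alone 7 members were lower. The macrophages list lay at -0.42 with 2 of 24 members above 0 (camera adjusted p = 2.82e-06), MHC class II at -0.72 with 0 of 6 above 0 (adjusted p = 0.0103), mural cells at -0.43 (adjusted p = 0.00234, 1 member lower adjusted over the list alone), endothelium at -0.33 (adjusted p = 0.0275) and fibroblasts and matrix at -0.22 (adjusted p = 0.00859). Single libraries moved these values. Without wt female 3, which had the highest interferon and MHC class II scores, interferon response lay at -0.23 (adjusted p = 0.00300), MHC class II at -0.31 (adjusted p = 0.0771) and endothelium at -0.12 (adjusted p = 0.259). Without hoz female 2, which had the lowest mural and macrophage scores, macrophages lay at -0.21 (adjusted p = 0.0137), MHC class II at -0.46 (0.0929), mural cells at -0.25 (0.123), endothelium at -0.11 (0.705) and fibroblasts and matrix at -0.21 (0.225). Without hoz female 1, MHC class II lay at -1.62, macrophages at -0.75, fibroblasts and matrix at -0.33, and endothelium at -0.29 (adjusted p = 0.158). Without hoz female 3, mural cells lay at -0.72, endothelium at -0.57, fibroblasts and matrix at -0.44, and MHC class II at -0.50 (adjusted p = 0.167). Smaller shifts were called for ribosomal proteins (median -0.07, 50 genes, adjusted p = 0.00225), secreted growth factors and binding proteins (-0.08, 34 genes, adjusted p = 0.0121), mitochondrially encoded genes (0.15, 12 of 12 above 0, adjusted p = 0.0135), ion and water transport (0.07, adjusted p = 0.0142), neurons (0.51, adjusted p = 0.0468, beside the neuron score of hoz female 1) and the circadian clock (0.09, 20 genes, adjusted p = 0.0468). Each of these 12 calls was lost, at an adjusted p = 0.720 with an estimated correlation. Leaving out the 3 libraries that stand apart by their scores, a choice made after the scores were seen, left 2 lists called, with the endothelium median at 0.02. With the neuron score as a covariate the neurons median was -0.02, which that score, made from the same genes, brings about by construction. Without hoz female 2 there were 7 lists called. Without hoz female 3 the circadian clock lay at 0.017 (adjusted p = 0.410), ion and water transport at 0.031 (0.172) and neurons at 0.45 (0.213). Without hoz female 1 neurons lay at 0.080 (adjusted p = 0.689), mitochondrially encoded genes at 0.12 (0.0802), ribosomal proteins at -0.15 and secreted growth factors at -0.12. Without hoz female 2 ribosomal proteins lay at -0.0098 (adjusted p = 0.235), secreted growth factors at -0.13 (0.107), neurons at 0.78 and the clock at 0.14. The calls of neurons without wt female 1, 2 or 3 (adjusted p = 0.117, 0.106 and 0.0581), of the clock without wt female 1 or 3 (0.0893 and 0.107) and of mitochondrially encoded genes without wt female 3 (0.0771) were lost. Of the 12 list calls 10 were lost without some single library, and all 12 were lost or moved by over 1.5 times. Motile cilia (0.02) and calcium and TRP channels (0.05) had a mean of the opposite sign to the median, steroid synthesis (-0.01) and abhydrolases (-0.00) had a test direction opposite to it, and none of these was called.

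Over both sexes, Scd1, which makes monounsaturated fatty acids, was the 1 gene called besides Abhd2. It fell by 0.61 on the log2 scale (SE 0.0785, adjusted p = 0.0161), from 297 ± 58.9 to 202 ± 18.7 CPM in males and from 276 ± 4.77 to 173 ± 9.40 CPM in females (SD, n = 3), and all 6 hoz libraries lay below all 6 wt libraries. The next genes were not called: Pcsk2 (log2 fold change -0.38, adjusted p = 0.143), Col17a1 (-0.28, adjusted p = 0.455), and Dpysl2, a protein of growing axons (-0.74), Kcnq1ot1, an imprinted antisense RNA (0.58), and Vtn, vitronectin (-0.26), each with an adjusted p of 0.525. Kcnq1ot1 overlaps Kcnq1, and its reads cannot be told from those of that gene if strand was not used. The call of Scd1 was lost in 8 of the 12 fits that leave out 1 library, with adjusted p of 0.0900 without hoz male 1, 0.111 without hoz male 2, 0.0734, 0.179 and 0.0735 without wt female 1, 2 and 3, and 0.162, 0.0916 and 0.167 without hoz female 1, 2 and 3. Without wt male 3, 9 genes were called in place of 2. Reads could be split with the related Scd2.

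By lists, cholesterol synthesis lay at a median of -0.06 over both sexes with 2 of 23 members above 0 (camera adjusted p = 5.00e-05). The macrophages list lay at -0.18 (adjusted p = 0.00179), oligodendrocytes at -0.24, mural cells at -0.17 and secreted growth factors and binding proteins at -0.05 (each adjusted p = 0.0211), and erythroid at 0.30 (adjusted p = 0.0211). Fibroblasts and matrix lay at -0.14 (adjusted p = 0.0214), astrocytes at -0.21 (16 genes, adjusted p = 0.0297) and MHC class II at -0.34 (adjusted p = 0.0336). Without wt male 3 the mural cells median was 0.07 (adjusted p = 0.309), 8 of the 9 list calls were lost without some single library, and all 9 were lost or moved by over 1.5 times. Without wt male 3 also, cholesterol synthesis lay at -0.038 (adjusted p = 0.00807), fibroblasts and matrix at -0.048 (0.242), MHC class II at -0.17 (0.242) and secreted growth factors at -0.0033 (0.129). Without hoz female 2 macrophages lay at -0.081 (adjusted p = 0.131), mural cells at -0.094 (0.171), astrocytes at -0.11 (0.313) and MHC class II at -0.21 (0.171). Without wt male 1 astrocytes lay at -0.053 (adjusted p = 0.182), erythroid at 0.14 (0.126) and oligodendrocytes at -0.17 (0.0768), and without wt female 2 oligodendrocytes lay at -0.15 (0.146). Without hoz male 2 erythroid lay at 0.093 (adjusted p = 0.0692), but mural cells at -0.42, fibroblasts and matrix at -0.28 and secreted growth factors at -0.12, and without hoz female 1 MHC class II lay at -0.80, oligodendrocytes at -0.44 and macrophages at -0.35. All 9 calls were lost, at an adjusted p = 0.707 with an estimated correlation, or 0.778 for mural cells. 1 gene of the mural cells list and 1 of the steroid receptor list passed when adjusted over the list alone. Calcium and TRP channels, not called, had a median of 0.02 and a mean of -0.01.

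**Figure D2:**
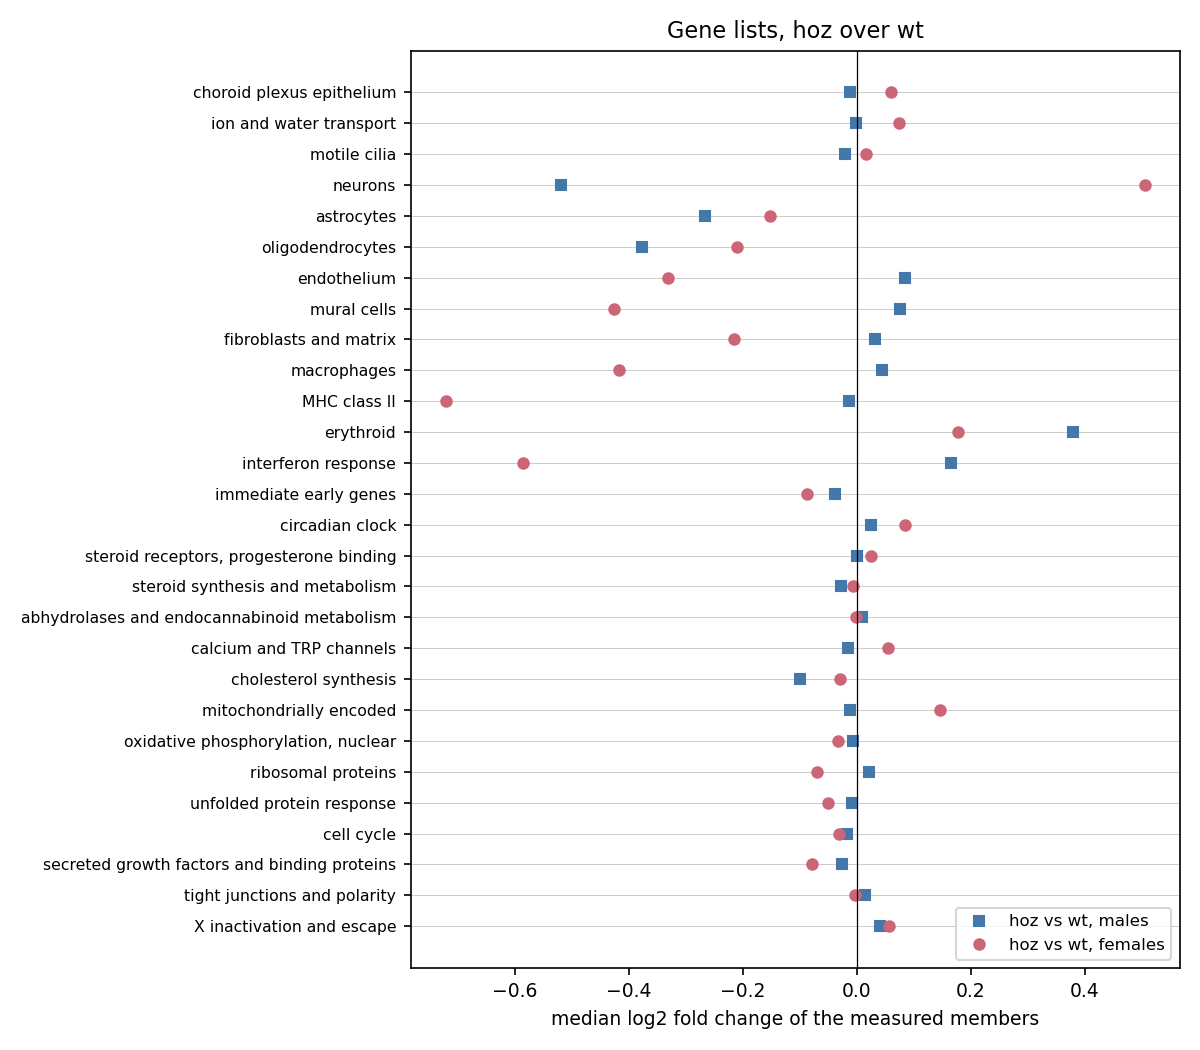
Median log2 fold change of hoz over wt (x axis) for 28 gene lists (y axis), in males (squares) and females (circles), each from 3 libraries against 3. Interferon response lay at 0.17 in males and -0.58 in females, and neurons at -0.52 and 0.51.

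Genotype effects of males and females were weakly related across genes. Over all 13857 genes, which are not independent replicates, the fold changes had a Pearson r of -0.00725 and a Spearman rho of 0.0573. Without Abhd2 the r was -0.0428 and the rho 0.0571. Over the 10141 genes of at least 5 CPM in wt males, also without Abhd2, the r was 0.0769 and the rho 0.107. At an unadjusted p under 0.05, 20 genes were higher in both sexes and 18, with Abhd2, lower in both, more than the 5.36 and 4.78 of independent lists (Fisher's exact test across genes, one-sided, p = 3.7e-07 and 1.4e-06), and 7 and 3 were opposite. That test takes the genes and the contrasts as independent, although the contrasts share each gene's variance estimate. Scd1 was lower in every hoz library than in every wt library of the same sex. The interaction was called for Ddx17 (log2 -0.54, SE 0.0783, adjusted p = 0.0490), whose level in males was 213 ± 8.62 CPM in wt and 228 ± 7.56 CPM in hoz. At an unadjusted p under 0.05 there were 505 genes. With relative log expression factors, or with limma voom, 0 genes were called, DESeq2 called 3, and in edgeR the call of Ddx17 was lost in 11 of the 12 fits that leave out 1 library, every one except that without wt male 3 (adjusted p = 0.00282, 7 genes called), with a highest adjusted p of 0.360 without wt female 2. Not called were Hspb1 (-0.66, adjusted p = 0.323) and, each at an adjusted p of 1.0, Inmt (-0.99), the interferon genes Rtp4 (-1.52) and Irf7 (-1.02), and Zc3h6 (0.93). In the interaction the motile cilia, abhydrolases and calcium channel lists had medians of 0.01, 0.01 and 0.04 and means below 0, astrocytes had a median of 0.08 with a test direction of lower, and none of these was called. Linked variants carried along with the knockout allele would cluster near Abhd2. With 1 gene called over both sexes besides Abhd2, the calls cannot test this. Of 81 tested genes within 10 Mb of it on chromosome 7, 7 passed an unadjusted p under 0.05 against 4.56 by chance (odds ratio 1.59, Fisher's exact test, two-sided, p = 0.223).

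More genes differed by sex than by genotype, and clock genes were among the largest differences between wt females in proestrus and wt males. By edgeR 365 genes were called, 188 higher and 177 lower in females, of which 345 were autosomal, 14 on X and 6 on Y. Of 20 clock genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone). Ciart, a repressor of the clock's activators, rose by 3.09 on the log2 scale (SE 0.261, adjusted p = 8.72e-06), from 1.11 ± 0.152 to 9.61 ± 1.14 CPM (SD, n = 3). The period genes Per2 (1.90, SE 0.159, adjusted p = 1.40e-05) and Per3 (1.36, SE 0.122) and the output gene Dbp (1.93, SE 0.214) rose, as did the E-box repressor Bhlhe41 (0.76), the output gene Hlf (0.76), the Rev-erb gene Nr1d2 (0.59), the cryptochrome Cry2 (0.48) and the output gene Tef. The activators were lower. Arntl, which encodes BMAL1, fell by 2.36 on the log2 scale (SE 0.317, adjusted p = 0.00242), Npas2 fell by 1.02 and Clock fell by 0.57 (SE 0.0634, adjusted p = 5.93e-05). The list's median was 0.54 (camera adjusted p = 1.67e-05, fry adjusted p = 5.47e-04), with an adjusted p = 0.118 with an estimated correlation.

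**Figure D3:**
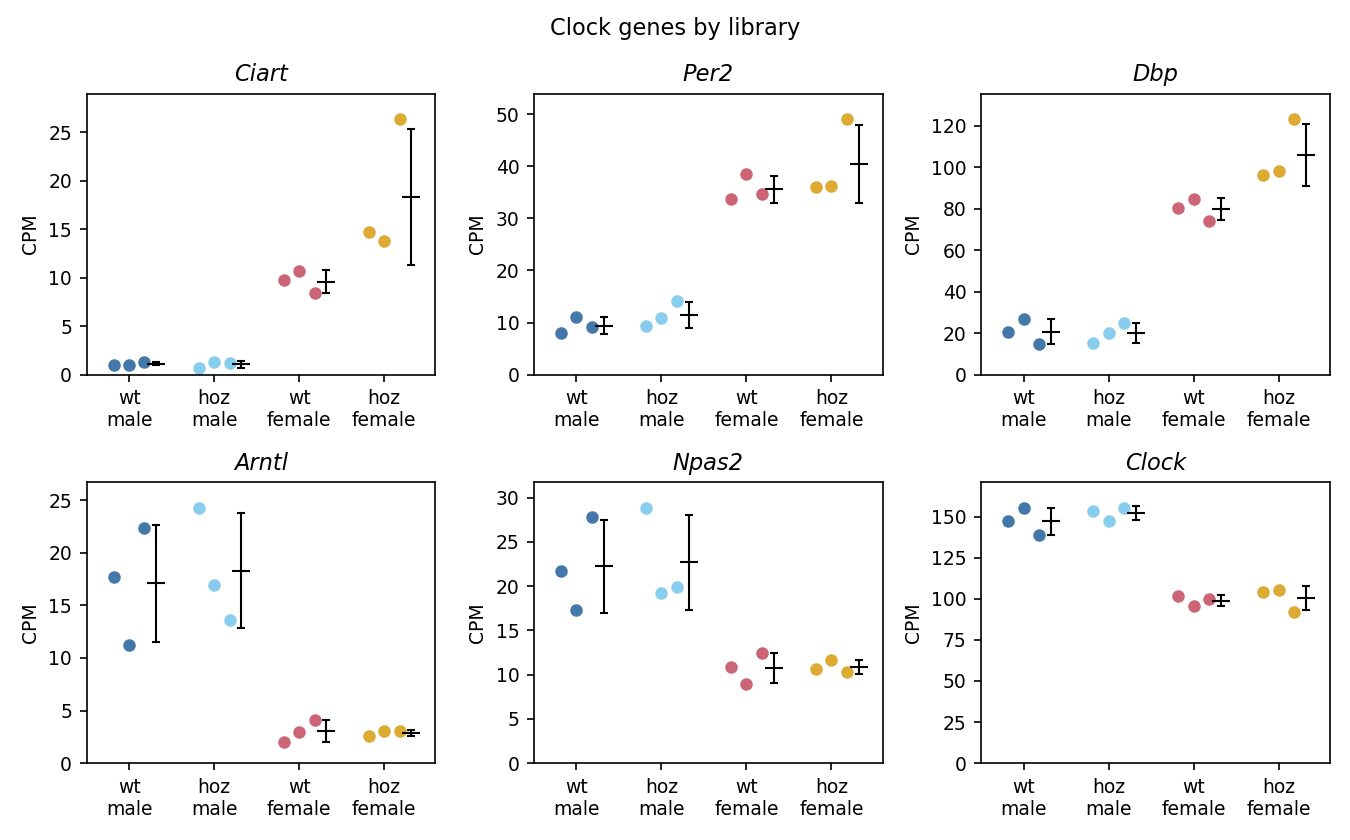
CPM per library (y axis) of Ciart, Per2, Dbp, Arntl, Npas2 and Clock in the 4 groups of 3 libraries (x axis), with a black dash at the mean and a bar of ± 1 SD. In every panel the female and male libraries of a genotype do not overlap, with Arntl at 3.03 ± 1.05 CPM in wt females and 17.1 ± 5.57 CPM in wt males.

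Some interferon genes rose in wt females. Of 23 measured, 6 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 4.16e-11, adjusted p = 0.227 with an estimated correlation). Examples are the antiviral genes Oas1a (2.07, adjusted p = 0.0180), Ifit3 (1.87, adjusted p = 0.00820) and Ifit1 (1.35), the interferon induced GTPase Gbp2 (1.18), Rtp4 (1.16) and the transcription factor Irf7 (0.69). Outside the list, the GTPases Iigp1 (1.92, adjusted p = 0.00211) and Gbp5 (2.03) and the class I antigen gene H2-Q6 (2.35, at 1.20 ± 0.982 CPM in females) rose too. Gbp2 and Gbp5 lost the call in 4 of the 6 fits that left out 1 library, H2-Q6 in 3, Rtp4 in 2 and Ifit3 in 1. Iigp1 kept it in all 6, and Oas1a was tested in only 2 of them. The authors' deposited table calls Ifit3, Iigp1, Gbp2, Gbp5 and Rtp4 but has no adjusted p for H2-Q6 or Oas1a. The 6 MHC class II genes had a median of 1.67 (camera adjusted p = 5.11e-06, adjusted p = 0.229 with an estimated correlation), with 0 called over all genes and 6 higher adjusted over the list alone. Both lists scored highest in wt female 3, and without it Ifit3 had an adjusted p of 0.0510 and the interferon median was 0.30. Vascular and stromal lists had medians above 0, with endothelium at 0.56 (camera adjusted p = 2.63e-04, Rgcc called at 0.76), mural cells at 0.32 (adjusted p = 0.00801) and fibroblasts and matrix at 0.22 (adjusted p = 0.0300, Islr called at 0.41), while neurons lay at -0.93 (adjusted p = 3.18e-04) beside the neuron score of wt male 1. These 4 had an adjusted p = 0.789 with an estimated correlation. Single libraries moved these values: endothelium scored -0.94 in wt male 2 and 0.50 in wt male 3, and its median was 0.21 without wt male 2 (adjusted p = 0.216), 1.14 without wt male 3 and 0.29 without wt female 3. Mural cells lay at 0.13 without wt male 2 (adjusted p = 0.426) and 0.88 without wt male 3. Fibroblasts and matrix lay at 0.50 without wt male 3 and lost the call without wt male 2, wt female 2 or wt female 3 (adjusted p = 0.430, 0.125 and 0.0800). Neurons lay at -0.31 without wt male 1 (adjusted p = 0.0636). The macrophages list was not called (0.23, adjusted p = 0.118).

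Of 26 genes of the unfolded protein response, 5 fell and 1 rose in wt females (10 and 2 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00292, adjusted p = 0.789 with an estimated correlation). The chaperone Hspa5 (BiP) fell by 0.47 (SE 0.0839, adjusted p = 0.00504), from 1618 ± 170.3 to 1166 ± 91.8 CPM, and Hsp90b1 fell by 0.38, the disulfide isomerases Pdia3 and Pdia6 by 0.34 and 0.45, and the secreted factor Manf by 0.52, while Herpud1, which acts in degradation of misfolded proteins, rose by 0.65 (adjusted p = 9.03e-04). Among channels, Cacna1h, a T-type calcium channel subunit, rose by 1.15 (SE 0.120, adjusted p = 2.90e-05), Orai1 by 0.42 and the mechanosensitive channel Piezo1 by 0.38, which makes 3 of 30 (4 adjusted over the list alone). Among 36 transport genes the sodium pump subunit Atp1b1 (0.27) and the folate carrier Slc19a1 (0.41) rose and the vitamin C transporter Slc23a2 fell by 0.25 (5 higher and 1 lower adjusted over the list alone). Of 34 growth factor genes, Wnt5b (1.43, adjusted p = 0.00253), Mdk (0.77) and Fgf1 (0.65) rose (6 higher and 2 lower adjusted over the list alone; median 0.14, camera adjusted p = 0.0291, adjusted p = 0.789 with an estimated correlation), a list call lost without wt male 2 (0.077, adjusted p = 0.235) or wt female 3 (adjusted p = 0.0800). The gene call of Mdk was lost in all 6 fits that left out 1 library and that of Fgf1 in 4 of 6, while Wnt5b kept its call. Single members of other lists were called. They were the cell adhesion gene Cdh1 (1.41), the cilium genes Dnah2 (0.33) and Iqub (-0.45) and the immediate early gene Ier3 (0.63). The membrane progesterone receptor Paqr5 (-0.29) and the anandamide hydrolase Faah (-0.76) were called too. Hsp90b1, Pdia3, Atp1b1, Slc19a1, Cdh1, Paqr5 and Faah lost the call in 4 of the 6 fits that left out 1 library. Slc23a2, Piezo1, Dnah2, Iqub and Ier3 lost it in 5 of 6 and Orai1 in 1, while Cacna1h, Herpud1 and Hspa5 kept it. Of the 6 single members, the authors' deposited table calls all but Dnah2 and Paqr5. The motile cilia, astrocytes, abhydrolases and tight junctions lists had a mean of the opposite sign to the median (-0.05, -0.02, 0.01 and -0.00), steroid hormone receptors (0.03) and ribosomal proteins (-0.00) had a test direction opposite to it, and none of these was called.

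The largest fold change among called autosomal genes was that of B4galnt3, a glycosyltransferase, 40.5-fold higher in wt females (log2 5.34, SE 0.496, adjusted p = 1.76e-04), at 15.7 ± 9.55 CPM against 0.396 ± 0.108 CPM (SD, n = 3). The X-linked matrix proteoglycan gene Bgn rose by 2.59. Spon2 fell by 3.18, Arhgap20 by 1.87, Sphkap by 1.58, Rd3l by 1.51 and the adenylyl cyclase Adcy1 by 1.42. B4galnt3, Arhgap20, Sphkap and Rd3l overlap other genes. Of 50 genes named by the rule and called in this contrast, 24 were called in every fit that left out 1 library, including Ciart, Per2, Per3, Dbp, Arntl, Clock, B4galnt3, Iigp1, Cacna1h, Herpud1, Hspa5 and Wnt5b. Another 25 lost the call in at least 1 fit, and Oas1a was not tested in some. Rgcc and Mdk lost it in all 6 fits, and Adcy1, Slc23a2, Dnah2, Iqub, Ier3 and Piezo1 in 5 of 6. It was lost in 4 of 6 for Bgn, Gbp2, Gbp5, Cdh1, Slc19a1, Atp1b1, Paqr5, Faah, Pdia3, Hsp90b1 and Fgf1, and in 3 for H2-Q6. The number of genes lost was 19, 15 and 7 without wt male 1, 2 and 3 and 13, 18 and 24 without wt female 1, 2 and 3. The count of called genes was 174 without wt male 1, and 243, 184 and 171 without wt female 1, 2 and 3. With reads thinned to equal totals, chosen after the depths were seen, 238 genes were called, 207 of them among the 365, and without the 3 libraries that stand apart there were 76, of which 73 were among the 365. The authors' deposited table calls 390, of which 288 are among the 365.

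Clock genes differed between the sexes without Abhd2 too. Between hoz females and hoz males edgeR called 371 genes, 224 higher and 147 lower, with 356 autosomal, 10 on X and 5 on Y. Of 20 clock genes 10 rose and 3 fell (12 and 5 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 7.15e-06, fry adjusted p = 1.42e-04, adjusted p = 0.0892 with an estimated correlation). Ciart rose by 3.95 (SE 0.255, adjusted p = 3.20e-07), Dbp by 2.34, Per2 by 1.76, Per3 by 1.22 and Bhlhe41 by 1.15, and Arntl fell by 2.66 (SE 0.365, adjusted p = 0.00252). All 12 clock genes called in wt were called here in the same direction. Per1, which rose by 1.71 (adjusted p = 0.0369), was not called in wt (0.99, adjusted p = 0.202). It stood at 53.1, 69.5 and 130 CPM in hoz female 1, 2 and 3, and at 56.2, 65.2 and 52.8 CPM in the wt females. Its call in hoz was lost in 4 of the 6 fits that left out 1 library. The interaction of sex and genotype was not called for any clock gene, and the clock list had 0 members called there adjusted over the list alone. Across the contrasts, which share no library but share each gene's variance estimate, 105 genes were higher and 88 lower in females of both genotypes, against 3.04 and 1.88 for independent lists, and 0 were opposite. Across 9822 autosomal genes of at least 5 CPM the fold changes had a Pearson r of 0.677, and over all 13377 autosomal and mitochondrial genes 0.364.

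**Figure D4:**
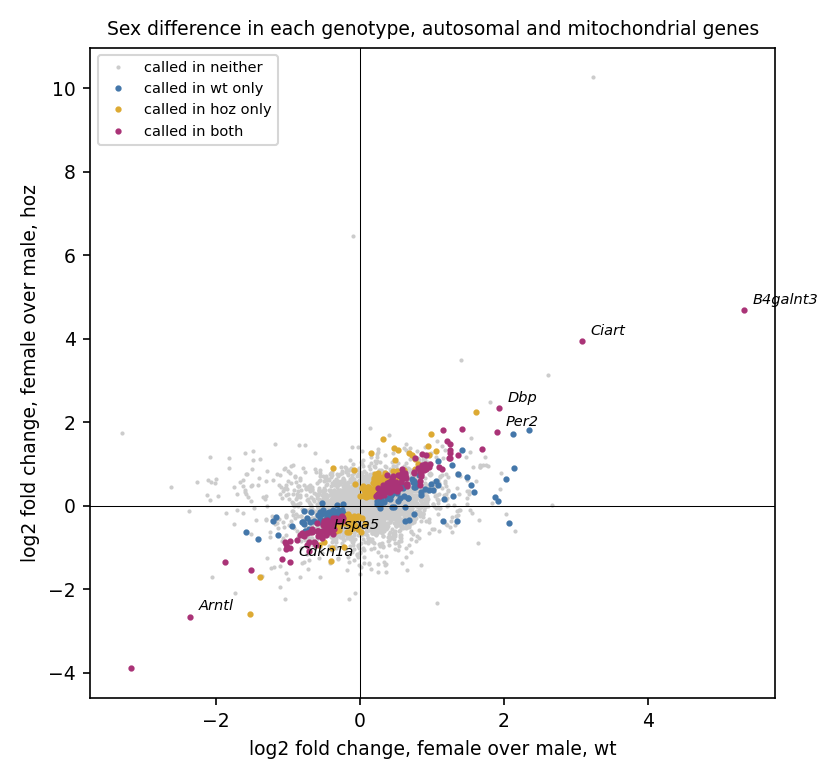
Log2 fold change of females over males in wt (x axis) against hoz (y axis), 1 point per autosomal or mitochondrial gene, colored by whether edgeR called it in neither contrast, wt, hoz or both. Genes called in both lie along the diagonal, with B4galnt3 at 5.34 and 4.68, Ciart at 3.09 and 3.95 and Arntl at -2.36 and -2.66.

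Between hoz females and hoz males, single genes of protein folding, transport and channel lists passed the test. In the unfolded protein response list 6 of 26 fell and 1 rose (13 and 3 adjusted over the list alone; median -0.23, camera adjusted p = 9.06e-05, adjusted p = 0.697 with an estimated correlation). Hspa5 fell by 0.70 (SE 0.0844, adjusted p = 1.09e-04), Manf by 0.76 and Creld2 by 0.64, and Herpud1 rose by 0.48. Of 36 transport genes 5 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.00277, adjusted p = 0.697 with an estimated correlation), among them the chloride channel Clcn2 (0.69), the kinase Wnk4 (0.63), Slc19a1 (0.55) and the carbonic anhydrase Car14 (0.40). Of 30 channel genes 4 rose (4 adjusted over the list alone; median 0.10, camera adjusted p = 0.0185, adjusted p = 0.801 with an estimated correlation): Cacna1h (1.82, adjusted p = 3.20e-07), Piezo1 (0.75), Orai1 (0.32) and Trpm3 (0.32). The epithelium list had 2 of 36 higher, Trpm3 and Ace (0.24), and 5 adjusted over the list alone (median 0.05, camera adjusted p = 0.0320, adjusted p = 0.841 with an estimated correlation). MHC class II lay at 0.94 (camera adjusted p = 0.0149, adjusted p = 0.799 with an estimated correlation), a value set by hoz female 1, which scored 0.88 against -0.33 and -0.26 in hoz female 2 and 3, and without which the median was 0.052 (adjusted p = 0.359). Ribosomal proteins at -0.09 (adjusted p = 8.96e-04) and macrophages at -0.17 (adjusted p = 0.00955) both had an adjusted p = 0.991 with an estimated correlation. Without hoz female 2 the medians were 0.0060 for macrophages (adjusted p = 0.449), -0.049 for ribosomal proteins (0.121) and 0.022 for epithelium (0.119). Without hoz male 1 they were 0.060 for channels (adjusted p = 0.177), 0.021 for epithelium (0.146), 0.049 for transport (0.0443) and -0.059 for ribosomal proteins (0.0443). Without hoz female 1 macrophages lay at -0.56, ribosomal proteins at -0.17 and channels at 0.050. Without hoz male 3 macrophages lay at -0.32 and epithelium at 0.092, without hoz male 2 macrophages lay at -0.0093 (adjusted p = 0.115) and epithelium at 0.035 (0.116), and without hoz female 3 the calls of channels and macrophages were lost (0.0532). In all, 5 of the 10 list calls of this contrast were lost without some single library and 6 were lost or moved by over 1.5 times. Interferon response lay at -0.13 with 0 of 23 called by edgeR. Fibroblasts and matrix had a median of 0.04 and a mean of -0.14, tight junctions of -0.01 and 0.04, and mural cells lay at -0.27 with a test direction of higher, as did abhydrolases at a median of -0.00, and none of these was called.

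Single genes of other kinds repeated or were added. B4galnt3 was 25.7-fold higher in hoz females (log2 4.68, SE 0.521, adjusted p = 5.05e-04), Wnt5b rose by 1.85, Fgf1 by 0.67, Ier3 by 0.73 and Islr by 0.32, Erich5 by 2.24 and Themis3 by 1.61. Spon2 fell by 3.89, Rd3l by 1.55, Arhgap20 by 1.34, the neurofilament gene Nefh by 1.70, the cell cycle inhibitor Cdkn1a by 1.35 (adjusted p = 3.33e-04) and the vessel growth factor Angpt1 by 1.33. Paqr9, of the progestin receptor family, rose by 0.57 (adjusted p = 7.97e-04) and Tctex1d4 by 0.59, while the steroid receptor co-chaperone Fkbp4 fell by 0.25, the lipase Ddhd1 by 0.26 and the polarity gene Llgl2 by 0.30. Of 47 genes named by the rule and called, 25 were called in every fit that left out 1 library, and 22 lost the call in at least 1. Nefh, Tctex1d4, Fkbp4 and Ddhd1 lost it in all 6 fits. Erich5, Themis3, Arhgap20, Ace, Wnk4, Fgf1 and Llgl2 lost it in 5 of 6. It was lost in 4 of 6 for Per1, Clcn2, Islr, Ier3 and Orai1, and in 3 for Spon2 and Angpt1. The number of genes lost was 14, 18 and 12 without hoz male 1, 2 and 3 and 14, 18 and 15 without hoz female 1, 2 and 3. The count of called genes was 208 and 204 without hoz male 1 and 2, and 246, 223 and 200 without hoz female 1, 2 and 3. Without the 3 libraries that stand apart it was 182, of which 166 were among the 371. The authors' deposited table calls 458, of which 314 are among the 371.

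Xist and the Y genes separated the male and female groups as labelled. Xist, the RNA that silences an X chromosome, rose by 8.39 in wt females (SE 0.338, adjusted p = 5.52e-07) and 7.77 in hoz females, at 107 ± 17.9 and 113 ± 27.6 CPM (SD, n = 3). Genes that escape X inactivation rose in both genotypes: Kdm6a by 0.86 in wt and 0.84 in hoz, Eif2s3x by 0.62 and 0.65, Kdm5c by 0.50 and 0.39, and Ddx3x by 0.45 and 0.50. In that list 5 of 14 rose in each genotype (6 in wt and 9 in hoz adjusted over the list alone), with medians of 0.39 and 0.44 and an adjusted p = 0.00352 and 0.00330 with an estimated correlation. The other 9 were called in neither: in wt and hoz, Jpx lay at 0.59 and 1.0, Ftx at 0.21 and 0.76, Pbdc1 at 0.19 and 0.31, Slc6a6 at 0.33 and 0.38, Utp14a at 0.04 and 0.02, Car5b at -0.03 and 0.01, Mid1 at -0.02 and -0.18, Tsix at -0.04 and -0.11, and the remaining gene, which has a clone symbol, at 0.49 and 0.51. The Y genes Uty, Kdm5d, Eif2s3y and Ddx3y had 0 reads in all females. Against a limit of 3 reads over the group they were at least 559, 486, 111 and 3182-fold lower in wt females and at least 322, 263, 73.7 and 1652-fold lower in hoz females, and the median of these bounds was 9.03 and 8.19 in log2. The camera call of the Y linked list held, with an adjusted p = 0.00118 with an estimated correlation in wt and 0.00173 in hoz.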

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

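The tests of clock phase and of collection hour, of a single library and of macrophages behind the interferon genes, and of gene length and vascular tissue behind the male split were chosen only after the result was seen, as were the thinning of reads, the gene length slope and the removal of 3 libraries. The interaction of sex and genotype was called for 1 gene and 9 lists, and neither count held: 0 lists were called with an estimated correlation or with fry. Ddx17 had an interaction of -0.54 in log2 (SE 0.0783, edgeR adjusted p = 0.0490), a call lost in 11 of the 12 fits that leave out 1 library, with relative log expression factors and with limma voom. The interferon response list had a median interaction of -0.74 (camera adjusted p = 3.62e-14, adjusted p = 0.505 with an estimated correlation), with 11 members lower adjusted over the list alone. The other 8 had an adjusted p = 0.775 with an estimated correlation. Neurons lay at 1.03 with 25 of 25 members above 0 (camera adjusted p = 4.00e-07). In that list wt male 1 scored 1.11 and hoz female 1 scored 0.60. Its median was 0.51 without wt male 1, 0.60 without hoz female 1, 0.65 without hoz male 3 and 1.55 without hoz male 2. With the neuron score as a covariate it was 0.065, but that score is made from the same genes and removes the difference by construction. Of the 9 list calls 6 were lost without some single library, and all 9 were lost or moved by over 1.5 times: without wt female 3 interferon response lay at -0.29 and MHC class II at -0.28 (adjusted p = 0.169), without hoz male 2 mural cells lay at -0.0099 (0.367), fibroblasts and matrix at -0.081 (0.275) and macrophages at -0.22, without wt male 3 ribosomal proteins lay at 0.037 (0.806), without hoz male 1 ion and water transport lay at 0.052 (0.123), and without wt male 1 mitochondrially encoded genes lay at 0.072 (0.216). Others grew: mural cells lay at -1.12 and mitochondrially encoded genes at 0.29 without wt male 3, MHC class II lay at -1.61, macrophages at -0.87 and ribosomal proteins at -0.15 without hoz female 1, and mural cells lay at -0.84 without hoz female 3. Macrophages lay at -0.44 (adjusted p = 4.75e-06) and ribosomal proteins at -0.074 (adjusted p = 6.63e-05). Ion and water transport lay at 0.095 (adjusted p = 0.00905), mitochondrially encoded genes at 0.15 (adjusted p = 0.0210), and mural cells at -0.50 (adjusted p = 0.0203). MHC class II lay at -0.72 (adjusted p = 0.0319) and fibroblasts and matrix at -0.29 (adjusted p = 0.0333).

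Clock genes differed between females and males in both genotypes. Depth, carried over brain or stromal tissue, and gene length bias were argued against as whole causes: of 12 clock genes called in wt, 12 stayed called with reads thinned to equal totals, 11 with the neuron or the fibroblast score as a covariate, and 12 with the gene length slope as a covariate. A different clock phase at collection could not be settled: the 10 genes of the E-box arm lay 1.69 above the 5 genes of the arm repressed by Rev-erb in wt (medians 1.12 and -0.57, or 1.24 and -0.59 in hoz), but the arms hold genes whose direction had been seen and were widened after a first result. Against the direction of their arms lay Nr1d1 (-0.14, adjusted p = 0.632) and Cry1 (0.22, adjusted p = 0.344) in wt, neither called. Whether such a shift would come from sex, proestrus, the hour of collection or separate handling of the sexes cannot be told apart. The labels name no batch, and the library titles run through all males before all females. The protocols place all animals around 10 in the morning, but 0 of the libraries have an hour of their own in the labels. All females were in proestrus.

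Some interferon genes rose in wt females against wt males, with a list median of 0.69. Without wt female 3, the library with the highest score, the median was 0.30, between the bounds set for a single library as the cause. More macrophages in these pieces also could not be settled, with a macrophage median of 0.23, nor could depth, with an interferon median of 0.46 and a standard error of 0.179 after thinning to equal totals. An infection or other exposure of a single animal was not tested, and the sex difference itself stays open.

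The male libraries split in a way that crosses genotype. Setting wt male 1, wt male 2 and hoz male 1 against the rest called 900 genes where the genotypes called 1. Gene length bias could not be settled: the fold changes followed gene length across genes with a Spearman rho of 0.391, and the 328 genes on the side of the other libraries had a median length of 7132.5 bases against 1604.5 for the 572 on the opposite side, but a link with length had been seen before the test. More vascular and stromal tissue in some pieces could not be settled either: the endothelium, mural and fibroblast lists together had a median of 0.72 (standard error over genes 0.0839), but hoz male 3 scored -0.38, -0.43 and -0.15 in them, below the -0.24, -0.18 and -0.072 of wt male 1 on the opposite side. Depth could not be settled, since 517 genes were called after thinning, and a fit with the length slope was void because that slope has a correlation of 0.931 with the split.

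For each comparison, other splits of the same libraries were fitted beside the real one. Every count of splits below includes the real one. In males 3 of 10 splits called at least the real 1 gene, with a highest of 900. In females the real split was the only 1 of 10 to call at least its 2 genes, with a highest other of 0. Between the sexes the real split was again the only 1 of 10 in wt (365 real, highest other 0) and in hoz (371 real, highest other 0). Each other split there put males and females in both arms, so genes that differ by sex widened the spread within arms. Its 0 calls therefore lend no support to the real counts. With 10 splits no share under 0.05 can be reached. Over both sexes 7 of 100 splits called at least the real 2 genes, with a highest of 506. For the interaction 14 of 100 called at least the real 1, with a highest of 218. Chance was therefore not excluded for these counts. The real 2 genes include Abhd2, the inactivated gene, and the counts say nothing about its own fall. The splits with 506 and 218 genes set wt male 1, wt male 2 and hoz male 1 on 1 side, as did the male split with 900. They are thus not separate from that split. Splits that call so many more genes than the real one point to a structure of the samples.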

How the results depend on the processing

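Thinning of reads, the gene length slope, the removal of wt male 1, wt female 3 and hoz female 2, and the unadjusted threshold for sharing and for chromosome 7 were chosen only after the data were seen. The fall of Abhd2 stayed called with every library left out in turn, at -5.35 to -5.17 in males, -5.53 to -5.40 in females and -5.41 to -5.32 over both sexes. No paired analysis was possible because the replicate numbers follow the order of listing and no label links a library of 1 group to one of another. The fit on only the groups compared does not apply to both sexes or the interaction, and no pseudocount alternative applies to counts. Depth limits the hoz females most.

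Counts below are called genes, and the cause was not tested unless the setting names it. A fold of at least 1.5 left 1 in females, 145 and 150 between the sexes in wt and hoz, and 0 for the interaction. Relative log expression factors and limma voom gave 0 for the interaction. With no filter there were 2 in males, 6 in females, 5 over both sexes and 2 for the interaction. DESeq2 gave 4, 7, 13 and 3 for these, and voom with sample weights 3 in males. A fit on only the groups compared gave 39 in females and 211 between the sexes in wt. The neuron score as a covariate gave 4 in females and 166 between the sexes in wt, and for the interaction a different gene in place of Ddx17. The fibroblast score gave 5 over both sexes, 563 between the sexes in hoz and 0 for the interaction. Thinned reads gave 5 in females, 238 between the sexes in wt and 2 for the interaction. The gene length slope gave 2 in males, 14 in females, 5 over both sexes, 964 and 645 between the sexes in wt and hoz, and 2 for the interaction. Without the 3 libraries there were 1 in females, 1 over both sexes, 76 and 182 between the sexes in wt and hoz, and 0 for the interaction. With 1 library left out the ranges were 1 to 8 in males, 1 to 3 in females, 1 to 9 over both sexes, 171 to 543 and 200 to 255 between the sexes in wt and hoz, and 0 to 7 for the interaction, each highest value except those of females and of the hoz sex contrast being the fit without wt male 3. At an unadjusted p under 0.05, 38 genes, Abhd2 among them, passed in both sexes in the same direction, some of which chance alone would give.

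Lists called fell to 0 in males, females, both sexes and the interaction with camera's estimated correlation and with fry, and to 2 and 2 between the sexes in wt and hoz with the estimated correlation and 5 and 3 with fry. Thinned reads gave 3 lists in males and 2 over both sexes, the gene length slope 14 over both sexes, and leaving out the 3 libraries 3 in males, 2 in females and 3 over both sexes. With 1 library left out the ranges were 4 to 11 in males, 7 to 12 in females, 5 to 17 over both sexes, 9 to 18 and 8 to 11 between the sexes in wt and hoz, and 5 to 12 for the interaction. Medians that turned sign were neurons with the neuron score as a covariate, -0.020 in females and 0.056 between the sexes in wt, which that covariate removes by construction. With 1 library left out, mural cells over both sexes lay between -0.42 and 0.074 and ribosomal proteins in the interaction between -0.15 and 0.037, the positive values being those without wt male 3. Between the sexes in hoz, macrophages lay between -0.56 and 0.0060, the latter without hoz female 2. Without the 3 libraries macrophages lay at 0.010 there, endothelium in females at 0.019 and MHC class II in the interaction at 0.064. With the gene length slope, ribosomal proteins in females lay at 0.028. The cause of these was not tested.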

Other observations

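The fits with the gene length slope and with thinned reads, and the tests of heat shock and glucocorticoid genes, were chosen only after the result was seen, and the fatty acid list was chosen after Scd1 and Scd2 were seen. With the gene length slope as a covariate, edgeR called Scd1 at -0.67 over both sexes (adjusted p = 7.37e-09), its relative Scd2 at -0.25 (adjusted p = 0.0220, 0.789 without the covariate), Polr3k, a subunit of RNA polymerase III, at 0.33 (adjusted p = 0.00283) and Dpysl2 at -0.82 (adjusted p = 0.0287). The slope moves with genotype in females, with a correlation of 0.723 and no overlap (-0.016 to -0.012 in wt, -0.0058 to 0.044 in hoz), against 0.059 in males. Fold changes over both sexes followed gene length with a Spearman rho of 0.181 across genes. Calls of this fit that use females may therefore come from the slope, and genes called in females alone are left out. With thinned reads, Hspb1 was called in females (-0.71, adjusted p = 0.00771) and in the interaction (-0.94, adjusted p = 0.0263). Scd1 (-0.70) and Ciart (1.09) were also called in females, each with an adjusted p of 0.0446. Ciart had 9.79, 10.7 and 8.39 CPM in the wt females and 14.7, 13.8 and 26.4 CPM in the hoz females, and with all reads it was 0.91 (adjusted p = 0.559), or 0.58 without hoz female 3 (adjusted p = 0.832), the shallowest library and the one set apart by the third principal component.

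A lower synthesis of fatty acids with Scd1 was tested on 25 genes of fatty acid synthesis and targets of SREBP1. Their median over both sexes was -0.032 with 8 above 0 (camera p = 0.0929 with an estimated correlation). The median's standard error of 0.0223 does not set it apart from the bound of -0.05 fixed before the test, and 17 members lay below 0, so the hypothesis stays open. In males the median was -0.06 with 5 above 0 (p = 0.0307 with an estimated correlation) and in females 0.01 (p = 0.501).

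A lower heat shock response in hoz females could not be settled. The median of 18 heat shock genes was -0.10 with 2 above 0 (camera p = 0.0770 with an estimated correlation, fry p = 0.0293), against 0.021 with 15 above 0 in males (p = 0.369 with an estimated correlation). The interaction had a median of -0.11 with 1 above 0 (p = 0.0496 with an estimated correlation, fry p = 0.0383), not adjusted for the lists and contrasts tried. Between hoz females and hoz males it was -0.16 with 1 above 0 (p = 0.0245 with an estimated correlation, fry p = 0.00207). Higher glucocorticoid exposure of the females could not be settled either. The median of 20 measured target genes was 0.18 in wt with 16 above 0 (p = 0.122 with an estimated correlation, fry p = 0.0430) and 0.26 in hoz with 14 above 0 (p = 0.116 with an estimated correlation, fry p = 0.0280).

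Reads of pituitary hormone genes, which are not choroid plexus genes, varied between libraries. Gh lay at 12.5 CPM in wt male 1, 10.1 in hoz female 2, 9.26 in wt female 2, 3.27 in wt female 3, 2.68 in hoz female 3, 2.45 in wt male 3 and at most 0.874 in the others. Prl lay at 17.1 CPM in hoz female 2, 13.7 in wt female 2, 5.02 in hoz female 3, 2.89 in wt female 3, 1.53 in wt male 1, and 0 in every hoz male. Pomc lay at 8.15 CPM in hoz female 2, 2.55 in wt female 2 and at most 0.767 in the others.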
